A study of Mus musculus with 20 samples.

How the data were processed

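Messenger RNA was measured in 20 mouse hearts, 2 in each of 10 groups (see Results). Total RNA was isolated with the miRNeasy Mini kit and libraries were made with the TruSeq Stranded mRNA kit. Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 with TopHat2 2.1.1 and Bowtie2, whose version is not given, and gene values were computed with Cuffdiff 2.2.1. The deposited values are FPKM, 1 table of 23284 genes per heart, of which 17793 were above 0 in at least 1 heart. The tables hold no fragment counts, and sequence reads were not used here.

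The values were checked before use. The sum of FPKM per heart was 579596 to 713671, the 10 most abundant genes took 21.3% to 24.5% of it, and median-ratio scaling factors were 0.989 to 1.01. No 2 tables were identical. The labels do not give sex; the Y-linked gene Ddx3y was 24.4 to 34.8 FPKM and Xist at most 0.0358 FPKM, so each heart was read as male. Absolute depth is not given in the sources used here; relative depth was estimated from the steps between the lowest values of each gene with at least 3 zeros. Gene positions are those of GENCODE M21 for the same genome build.

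Genes with a mean of at least 0.5 FPKM over the 20 hearts were kept, 12589 in number, and analysed as log2(FPKM + 0.5). One linear model with a mean for each of the 10 groups was fitted in limma 3.58.1 under R 4.3.3, with a prior variance that follows the mean (the trend option), 10 residual degrees of freedom and a median prior of 3.81 degrees of freedom. Each comparison was a contrast of group means, with equal weight to the times it averages, and the Benjamini-Hochberg (BH) adjusted p had to be under 0.05. Log2 differences carry the standard error (SE) of that model, and FPKM are given as mean ± SD over hearts. The comparisons were TAC against sham in each genotype over both times and at each time, CKO against control over all stages, at the end of tamoxifen, in sham hearts and in TAC hearts, the difference of the TAC responses between genotypes and between times, and the change of the genotype difference between the end of tamoxifen and sham. CKO against control in TAC hearts at each time, and the difference between genotypes in the change with time, were added after the data were seen.

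Gene lists were fixed for pathways and cell types of the heart, 40 in number with 792 genes, and 37 with at least 5 measured members were tested with camera, at a correlation between members of 0.01 and again with the correlation estimated from the data, adjusted by BH over the lists of a comparison. Members of a list that passed limma are counted, adjusted over all genes and over the list alone. Limma takes hearts as replicates, while camera at 0.01 takes genes.

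Named genes follow a rule. Among genes past the threshold with a mean of at least 1 FPKM in the compared hearts, and without overlap of the compared hearts at any time, the 10 largest rises and 10 largest falls are named, together with up to 4 members with the smallest p of each list that passed camera, and Wnt5a and Esr1 in every case. For differences of responses the condition on overlap was dropped, and where no gene passed, the 5 smallest p are named. Clone-named and predicted genes are counted and passed over. The text names a part of the genes this rule gives. The comparisons other than the 3 added ones, the lists, the rule and the alternatives not said to be added were chosen before the data were examined.

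The alternatives were pseudocounts of 0.1 and 1 FPKM, no filter and a filter of 3 FPKM, median-ratio scaling, quantile normalization, a fit of only the groups compared, a prior without trend, and each heart left out in turn. A fit without 1 heart leaves a group with 1 heart, which is assumed to vary like the other groups. Added after the data were seen were fits without the hearts with Myl7 of 10 FPKM or more. Sex could not be modelled, since all hearts were read as male.

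The fit was tested on simulated values with the spread of the real ones, with 200 of 12589 genes changed. Real hearts may give more false calls, since other groupings called up to 55 genes for the difference of responses. For TAC in control hearts it recovered 94% of genes changed 2-fold and 100% of those changed 4-fold, with 8 false among 202 calls; for the difference of responses between genotypes 80% and 96%, with 13 false among 189; and for the difference between genotypes in the change with time 25% and 75%, with 5 false among 105. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.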

Results

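The series measured messenger RNA in the hearts of 20 C57BL/6 mice by stranded RNA sequencing of total RNA. The mice were controls, with floxed alleles of Wnt5a, or CKO mice, which carried the floxed alleles together with a heart-muscle transgene that joins Cre recombinase to part of the oestrogen receptor (Esr1) and so removes floxed sequence after tamoxifen. Wnt5a encodes a secreted Wnt ligand, and the series title places it in a signalling axis with YAP, a transcriptional co-activator of the Hippo pathway, in the mechanical response of cardiac myocytes. Each genotype was sampled at the end of tamoxifen treatment, and at 2 and 4 weeks after a sham operation or after TAC (transverse aortic constriction, a surgical narrowing of the aorta that puts the left ventricle under pressure). That gave 10 groups of 2 hearts, and the labels name each library as a separate heart. The number in a heart's label names it here and occurs once. In controls, hearts 22 and 23 were taken at the end of tamoxifen, 12 and 16 after sham and 11 and 32 after TAC at 2 weeks, 6 and 7 after sham and 1 and 2 after TAC at 4 weeks. The matching CKO hearts were 21 and 24, then 14 and 15, 13 and 31 at 2 weeks, and 4 and 8, 3 and 41 at 4 weeks.

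Values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 23284 genes, of which 14788 to 15374 were above 0 in a heart. Fragments per library are not given here. Steps of 1 fragment among 1456 genes near the floor gave the depth of each library relative to the others, and 98.2% of 14771 such values lay within 5% of a whole multiple. Relative depth ran from 0.890 in heart 3 to 1.22 in heart 2, a ratio of 1.37. Pearson's r across genes between the 2 hearts of a group was 0.963 to 0.978, and between hearts of different groups 0.935 to 0.979; genes are not independent replicates.

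Wnt5a and Esr1 were examined in every heart to check the genotype labels. Wnt5a (mm10 chromosome 14, 28504750 to 28527448, plus strand) was lower in CKO hearts than in control hearts at each of the 5 stages. It stood at 2.69 ± 0.186 FPKM (SD, n = 2) in control and 1.97 ± 0.510 (SD, n = 2) in CKO hearts at the end of tamoxifen. In sham hearts of both times it was 3.396 ± 0.720 FPKM (SD, n = 4) in control and 2.01 ± 0.174 (SD, n = 4) in CKO mice. In TAC hearts it was 1.77 ± 0.205 (SD, n = 4) and 1.23 ± 0.342 (SD, n = 4). Esr1 (chromosome 10, 4611593 to 5005614, plus strand), whose sequence is part of the transgene, was 0.101 to 0.465 FPKM in the 10 control hearts and 197 to 931 FPKM in the 10 CKO hearts. No heart stood against its genotype label in either gene.

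**Figure D1:**
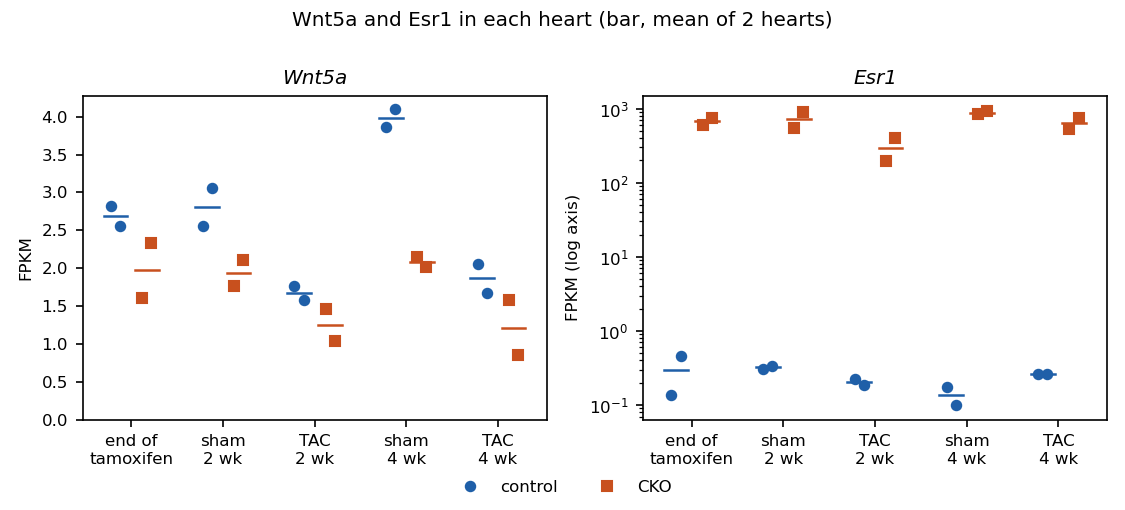
FPKM of Wnt5a and of Esr1 (log axis) in each of the 20 hearts, by stage and genotype, with a bar at the mean of the 2 hearts of a group. Wnt5a reached 4.11 FPKM in control and 2.33 FPKM in CKO hearts, and the Esr1 values of CKO hearts, 197 FPKM and more, lay far above those of control hearts.

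The Wnt5a difference averaged over the 5 stages was -0.49 ± 0.09 (log2, SE) and did not pass limma's test over all genes (limma adjusted p = 0.066, unadjusted 1.4e-04 for this gene named before the data were examined). It was -0.38 ± 0.21 at the end of tamoxifen (limma adjusted p = 1, unadjusted 0.091), -0.62 ± 0.15 in sham hearts (limma adjusted p = 1, unadjusted 9.6e-04) and -0.41 ± 0.15 in TAC hearts (limma adjusted p = 0.17, unadjusted 0.015). Without heart 3, the all-stage difference was -0.55 and passed (limma adjusted p = 0.013), as did that in TAC hearts, at -0.56 (limma adjusted p = 0.046). Without heart 41 that in TAC hearts was -0.26 (limma adjusted p = 0.44), and at the end of tamoxifen it was -0.17 without heart 21 and -0.59 without heart 24. Which exon is floxed is not given here, and a gene-level FPKM also counts reads from exons that remain after recombination. Esr1 passed in each genotype comparison, with a log2 difference of 9.65 ± 0.13 over all stages (limma adjusted p = 3.5e-15).

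TAC was first compared with sham in control hearts. Genes of the foetal and overload programme and of the extracellular matrix rose after TAC, and genes of fatty acid oxidation, the respiratory chain and adult contraction fell. Nppa (chromosome 4, 148000722 to 148002079), which encodes atrial natriuretic peptide, went from 189.6 ± 50.45 FPKM (SD, n = 4) in sham hearts to 6381 ± 3761 (SD, n = 4) after TAC. Acta1, the skeletal alpha-actin that foetal myocardium also makes, went from 104 ± 59.2 to 2944 ± 567. Postn (chromosome 3, 54361109 to 54391037), a matrix protein of activated fibroblasts, went from 16.3 ± 4.20 to 255 ± 153 FPKM. Ech1, an enzyme of mitochondrial and peroxisomal fatty acid oxidation, went from 2657 ± 270.2 to 1194 ± 328 FPKM. Ces1d (chromosome 8, 93166068 to 93197838), a carboxylesterase, went from 89.5 ± 33.4 to 9.18 ± 3.66.

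**Figure D2:**
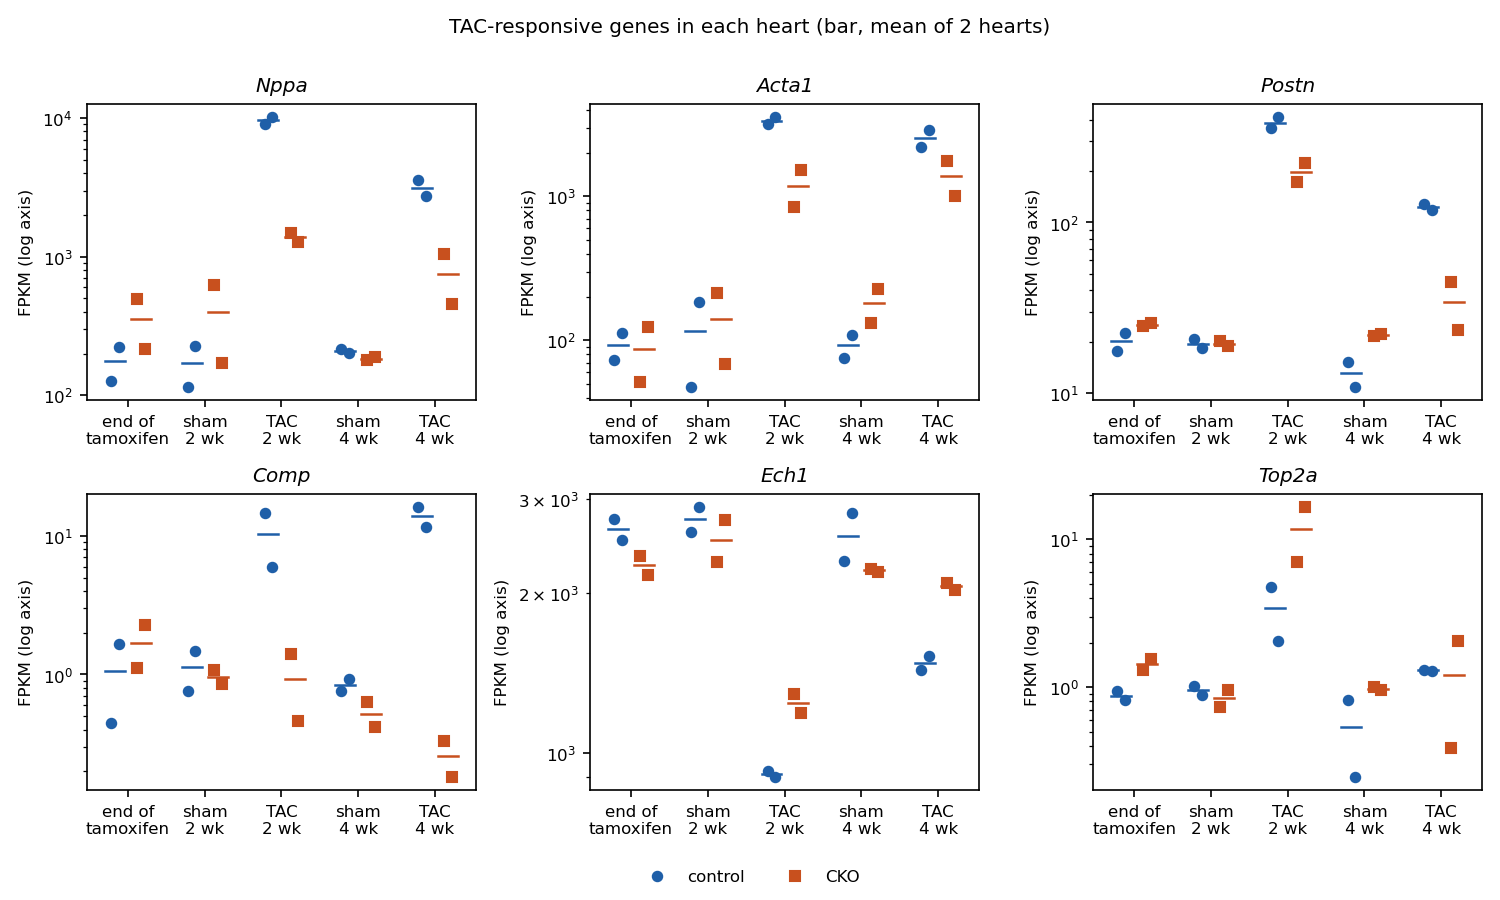
FPKM (log axis) of Nppa, Acta1, Postn, Comp, Ech1 and Top2a in each of the 20 hearts, by stage and genotype. Among TAC hearts, mean Comp was 12.0 FPKM in controls and 0.595 FPKM in CKO mice, and Nppa was 2761 FPKM or more in controls and at most 1489 FPKM in CKO mice.

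With limma, 3956 of 12589 genes passed at a BH-adjusted p under 0.05, 1927 higher and 2029 lower after TAC. Among the rises with the largest log2 differences were Acta1 at 4.96 ± 0.45 (SE, limma adjusted p = 3.8e-06), Nppa at 4.90 ± 0.39 (limma adjusted p = 1.4e-06). The matrix protein genes Cilp at 4.27 ± 0.27 and Postn at 3.74 ± 0.17 and Thbs4 at 3.36 were among the next. Ltbp2, Mfap4, Serpinb1c and Fmod had 3.06 to 3.34. Among the largest falls were those of Ces1d at -3.22 ± 0.20 (limma adjusted p = 1.7e-07), Retnla at -3.05, Penk at -2.87, the acyl-CoA thioesterase Acot1 at -2.57 and Pfkfb1, a regulator of glycolytic flux, at -2.36. Wnt5a itself fell by 0.76 ± 0.15 after TAC in control hearts (limma adjusted p = 0.0015).

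Of 19 measured foetal and overload genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 difference of 1.81. Ankrd1, a stretch-responsive muscle protein that is also a YAP target, rose by 3.00 ± 0.19, and Xirp2, an actin-binding protein, by 2.11 ± 0.12. The list passed camera (adjusted p = 3.7e-12; adjusted p = 0.21 with an estimated correlation). Of 46 measured matrix genes, 44 rose and 0 fell (44 and 1 adjusted over the list alone), with a median of 1.59 and Eln, which encodes elastin, at 1.86 ± 0.09. Camera gave the list an adjusted p = 7.5e-33 (adjusted p = 0.065 with an estimated correlation). Fibroblast markers moved with them, since 12 of 18 rose and 1 fell (13 and 1 adjusted over the list alone), for example Serpinf1 at 1.49 and Mmp2 at 1.29 (camera adjusted p = 4.4e-06; adjusted p = 0.30 with an estimated correlation). Among 25 macrophage markers 15 rose and 0 fell (16 and 0 adjusted over the list alone), including Trem2 at 2.07 and Lgals3 at 1.78 (camera adjusted p = 1.6e-04; adjusted p = 0.51 with an estimated correlation). The macrophage median was 0.63, and 0.41 without heart 16 or without the hearts with Myl7 of 10 FPKM or more. In all, 20 of 37 tested lists passed camera for TAC in control hearts, and 0 with an estimated correlation.

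Metabolic lists went down in the same hearts. Of 34 genes of fatty acid oxidation, 0 rose and 32 fell (0 and 33 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 7.9e-17; adjusted p = 0.32 with an estimated correlation). Ech1 stood at -1.19 ± 0.08 and Etfb, the electron transfer flavoprotein subunit, at -0.90 ± 0.08. Of 76 genes of oxidative phosphorylation, 61 fell and 0 rose (67 and 0 adjusted over the list alone), with a median of -0.34, for example Atp5e at -0.55 (camera adjusted p = 3.6e-16; adjusted p = 0.46 with an estimated correlation). In the tricarboxylic acid cycle 16 of 19 fell and 0 rose (16 and 0 adjusted over the list alone), with Sdha at -0.69 and Suclg2 at -0.55 (camera adjusted p = 4.1e-07; adjusted p = 0.49 with an estimated correlation). Of 25 genes of adult contraction and ion handling, 12 fell and 2 rose (12 and 3 adjusted over the list alone; camera adjusted p = 9.7e-04; adjusted p = 0.49 with an estimated correlation). Among them were Atp2a2, the calcium pump of the sarcoplasmic reticulum, at -0.94 ± 0.07 and the potassium channel gene Kcnd2 at -1.47 ± 0.13.

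Cell cycle and unfolded protein response genes also shifted. Of 33 cell cycle genes, 14 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 8.2e-05; adjusted p = 0.51 with an estimated correlation). Cdk1 stood at 1.07 ± 0.24, the replication helicase subunit Mcm3 at 0.82 ± 0.17 and, going down, the kinetochore gene Cenpf at -1.76 ± 0.19. With genes under a mean of 3 FPKM left out, the list's median was 0.18 against 0.61, and camera did not pass (adjusted p = 0.085); a pseudocount of 0.1 gave 0.93. Of 18 genes of the endoplasmic reticulum stress response, 12 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 1.2e-04; adjusted p = 0.51 with an estimated correlation). Herpud1 fell by 1.14 and the chaperone gene Hspa5 by 0.69. Of 22 measured YAP and TEAD target genes, 8 rose and 7 fell (12 and 7 adjusted over the list alone), and camera did not pass (adjusted p = 0.21). Ctgf, a matricellular growth factor on that list, rose by 2.99 ± 0.28, and Tgfb2 by 1.67 ± 0.17. Control hearts 11 (TAC) and 16 (sham) were among 5 with atrial transcripts, at Myl7 of 72.6 and 32.2 FPKM. Without the hearts with Myl7 of 10 FPKM or more, a removal chosen after seeing the data, 2383 genes passed, and Cdk1 (0.72, limma adjusted p = 0.097) and Mcm3 (0.70, limma adjusted p = 0.060) did not.

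At 2 weeks alone, 2998 genes passed limma in control hearts, 1386 higher and 1612 lower. Nppa rose by 5.89 ± 0.55, Acta1 by 5.15 ± 0.63 and Postn by 4.27 ± 0.23, and Lypd2 at -3.71 ± 0.66 and Ces1d at -3.20 ± 0.28 were among the falls. Here 43 of the 46 matrix genes rose and 0 fell (45 and 0 adjusted over the list alone), and camera passed under both correlations (adjusted p = 1.0e-36; adjusted p = 0.045 with an estimated correlation). At 4 weeks 1603 genes passed, 801 higher and 802 lower. Acta1 was higher by 4.78 ± 0.63, Cilp by 4.42 ± 0.39, Nppa by 3.91 ± 0.55 and the cartilage matrix gene Comp by 3.395 ± 0.46, and Retnla was lower at -3.38 ± 0.48. At this time 34 of 46 matrix genes rose and 2 fell (39 and 2 adjusted over the list alone; camera adjusted p = 1.1e-27; adjusted p = 0.11 with an estimated correlation). Of 34 genes of fatty acid oxidation, 10 fell and 0 rose (21 and 1 adjusted over the list alone; camera adjusted p = 1.9e-08; adjusted p = 0.55 with an estimated correlation). The calprotectin genes S100a8 and S100a9, abundant in neutrophils, were higher by 4.52 ± 1.14 (limma adjusted p = 0.020) and 4.59 ± 1.21 (limma adjusted p = 0.024). S100a8 did not pass without heart 1, 2 or 7, nor S100a9 without 1, 2, 6 or 7, with adjusted p values of up to 0.19 and 0.11. The 2-week count was 1618 without heart 16, 1707 without heart 32, 1119 without the hearts with high Myl7 and 1158 when only the groups compared were fitted. The 4-week count was 660, 695, 702 and 1053 without hearts 7, 1, 2 and 6, and 355 with only the groups compared. Lypd2 at 2 weeks was -5.93 with a pseudocount of 0.1 and did not pass without the hearts with high Myl7 (limma adjusted p = 0.11), nor S100a8 at 4 weeks with only the groups compared (limma adjusted p = 0.079).

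TAC was also compared with sham in CKO hearts. As a mean of both times, many matrix and cell cycle genes and part of the foetal genes rose, and many genes of fatty acid oxidation fell. Acta1 went from 161 ± 75.0 FPKM (SD, n = 4) in sham to 1281 ± 429 (SD, n = 4) in TAC hearts, Nppa from 291 ± 223 to 1065 ± 447 and Postn from 20.7 ± 1.51 to 116 ± 97.7. Ankrd1 went from 678 ± 249.9 to 2768 ± 540.2 FPKM and Ech1 from 2359 ± 256 to 1648 ± 476. Limma called 1147 genes, 532 higher and 615 lower.

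The largest rises in CKO hearts were those of Acta1 at 3.08 ± 0.45 (log2, SE, limma adjusted p = 0.0017), Ankrd1 at 2.08 ± 0.19 (limma adjusted p = 1.7e-04) and Nppa at 1.99 ± 0.39 (limma adjusted p = 0.0083). Postn stood at 1.93 ± 0.17 and Cilp at 1.75 ± 0.27. Mybpc2, a myosin-binding protein of fast skeletal muscle, the collagen gene Col8a1, Itgb1bp3, Ctgf and the natriuretic peptide gene Nppb rose by 1.51 to 1.72. Inmt at -2.17 ± 0.34 (limma adjusted p = 0.0024), the calcium channel subunit gene Cacng6 at -1.80, Rtn4r at -1.63 and Nmb at -1.57 were among the largest falls, with Cytl1, Pfkfb1, Cxcl14, Retnla and Phkg1 at -1.37 to -1.28. Esr1 was lower after TAC by -0.91 ± 0.21 (limma adjusted p = 0.017) and Wnt5a by -0.55 ± 0.15 (limma adjusted p = 0.034). The call of Wnt5a ended without heart 4, 8, 15, 31 or 41 (adjusted p up to 0.14) and that of Esr1 without heart 3, 8 or 15 (adjusted p up to 0.085). Retnla did not pass without heart 3, 4, 8, 15 or 31, Cytl1 without 4, 8, 14, 31 or 41, and Phkg1 without 15 or 31 (adjusted p up to 0.13). With only the groups compared, Nppa (limma adjusted p = 0.065), Ctgf (0.054), Itgb1bp3, Cytl1, Phkg1, Retnla, Esr1 and Wnt5a missed the threshold (adjusted p up to 0.13). So did Cytl1, Phkg1 and Wnt5a without the hearts with high Myl7 and Wnt5a with no filter on low values. With a pseudocount of 0.1, Cacng6 stood at -3.08.

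Of 19 foetal and overload genes, 9 rose and 0 fell in CKO hearts (13 and 0 adjusted over the list alone), with a median of 0.75 and Xirp2 at 1.01 ± 0.12. Camera gave an adjusted p = 1.3e-08 (adjusted p = 0.29 with an estimated correlation). Of 46 matrix genes, 27 rose and 0 fell (36 and 1 adjusted over the list alone), with a median of 0.70, Col5a2 at 0.92 and the fibrillin gene Fbn1 at 1.01 (camera adjusted p = 5.7e-20; adjusted p = 0.29 with an estimated correlation). Of 33 cell cycle genes, 22 rose and 0 fell (27 and 1 adjusted over the list alone), with a median of 1.01 (camera adjusted p = 2.4e-17; adjusted p = 0.29 with an estimated correlation). The ubiquitin ligase partner Ube2c rose by 1.85 ± 0.30, the mitotic motor gene Kif11 by 1.35 ± 0.21 and the spindle checkpoint gene Bub1b by 1.23 ± 0.18. With a filter of 3 FPKM that median was 0.37 (camera adjusted p = 2.7e-04). At 2 and 4 weeks alone the median was 1.39 and 0.02 for the matrix, 1.97 and 0.08 for the cell cycle and -0.68 and -0.11 for fatty acid oxidation. Among 34 genes of fatty acid oxidation 23 fell and 0 rose (31 and 0 adjusted over the list alone), with Ech1 at -0.56 ± 0.08 (camera adjusted p = 1.7e-17; adjusted p = 0.29 with an estimated correlation). Oxidative phosphorylation had 10 of 76 lower and 1 higher (15 and 1 adjusted over the list alone; camera adjusted p = 1.1e-10; adjusted p = 0.41 with an estimated correlation). The tricarboxylic acid cycle had 6 of 19 lower and 0 higher (16 and 0 adjusted over the list alone), with Sdha at -0.37 (camera adjusted p = 9.4e-08; adjusted p = 0.37 with an estimated correlation). Sdha did not pass without heart 8, 15, 31 or 41, or with only the groups compared (adjusted p up to 0.089). Of 25 adult contraction genes, 11 fell and 0 rose (12 and 1 adjusted over the list alone), with Atp2a2 at -0.58 ± 0.07 (camera adjusted p = 2.7e-06; adjusted p = 0.29 with an estimated correlation).

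Macrophage markers had 2 of 25 higher and 0 lower after TAC in CKO hearts (2 and 0 adjusted over the list alone; camera adjusted p = 2.1e-04; adjusted p = 0.46 with an estimated correlation). The macrophage median was 0.34; it was 0.58 and 0.59 without hearts 3 and 14, 0.22 without heart 8 and 0.21 without heart 41, where the list did not pass (adjusted p = 0.054). Interferon response genes had a median log2 difference of 0.74, with 1 of 35 higher and 0 lower (0 and 0 adjusted over the list alone). In limma 15 were higher at an unadjusted p under 0.05, and the list passed (camera adjusted p = 8.7e-08; adjusted p = 0.44 with an estimated correlation). The median was 0.27 without heart 41 (camera adjusted p = 0.017) and 1.34 without heart 3, its partner in the group. A single heart carried high values of interferon-gamma genes. Heart 41 had the GTPase genes Igtp at 623 FPKM against 7.77 to 31.2 FPKM in the other 19 hearts, and Irgm1 at 218 against at most 23.1 FPKM. Of the YAP and TEAD targets, 5 of 22 rose and 0 fell (6 and 4 adjusted over the list alone), and camera did not pass (adjusted p = 0.12). The count of 1147 genes was 351, 407, 531 and 737 without hearts 31, 15, 8 and 41, 728 without the hearts with high Myl7, and 313 when only the groups compared were fitted. A fit of the 8 hearts with 1 TAC effect for both times called 0 genes in limma, with 1999 at an unadjusted p under 0.05.

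At 2 weeks cell division genes led the rises in CKO hearts. Limma called 2424 genes, 1265 higher and 1159 lower. Ube2c rose by 3.52 ± 0.42 (limma adjusted p = 3.4e-04), Top2a, the topoisomerase of dividing cells, by 3.07 ± 0.47, the survivin gene Birc5 by 3.04 ± 0.53, Cep55 by 2.71 ± 0.25 and the proliferation marker gene Mki67 by 2.60 ± 0.33. Postn rose by 3.30 ± 0.23 and Acta1 by 3.22 ± 0.63. The falls were led by Lgals6 at -4.47 ± 1.01, the complement factor D gene Cfd at -2.77 ± 0.82, Penk at -2.50, Ces1d at -1.78 and Kcnv2 at -1.71. Of 33 cell cycle genes, 26 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 1.97 (camera adjusted p = 3.2e-19; adjusted p = 0.22 with an estimated correlation). With a filter of 3 FPKM the median was 0.63 (camera adjusted p = 1.6e-04). The matrix list had 38 of 46 genes higher and 0 lower (40 and 0 adjusted over the list alone; camera adjusted p = 3.7e-24; adjusted p = 0.17 with an estimated correlation). Of 34 genes of fatty acid oxidation, 30 fell and 0 rose (32 and 0 adjusted over the list alone; camera adjusted p = 4.4e-19; adjusted p = 0.22 with an estimated correlation). The count was 465 without heart 31, 605 without heart 15 and 15 with only the groups compared. Without either of those hearts Acta1 and Lgals6 did not pass (adjusted p up to 0.073), and Cfd did not pass without heart 13, 14 or 31 (adjusted p up to 0.25). With only the groups compared, Ube2c, Top2a, Birc5, Cep55, Mki67, Acta1, Penk, Kcnv2 and Cfd missed the threshold (adjusted p up to 0.16), and Cfd did so without the hearts with high Myl7 (-1.38, adjusted p = 0.30). Cfd was -4.16 without heart 15, and Lgals6 -6.71 with a pseudocount of 0.1.

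At 4 weeks 33 genes passed limma in CKO hearts, 19 higher and 14 lower, and 1601 had an unadjusted p under 0.05. Ankrd1 rose by 2.103 ± 0.27 (limma adjusted p = 0.014) and the ADP-ribosylhydrolase-like gene Adprhl1 by 0.88 ± 0.11. Also higher were the heat shock gene Hspa1l at 1.09 ± 0.18, Xirp2 at 1.05 ± 0.18 and Nrap, an anchoring protein of myofibril ends, at 0.76 ± 0.14. Cyp1a1 at -3.88 ± 0.73 (limma adjusted p = 0.045), Cacng6 at -2.54 ± 0.44, the water channel gene Aqp4 at -1.70 ± 0.32 and Kcnd2 at -1.14 ± 0.18 fell. Of 35 interferon response genes, 0 passed (0 adjusted over the list alone, and 1 at an unadjusted p under 0.05 in limma), and the list's median was 0.74 (camera adjusted p = 4.2e-06; adjusted p = 0.77 with an estimated correlation). Without heart 41 that median was -0.23 (camera adjusted p = 0.080), and without heart 3 it was 1.60. Of 46 matrix, 33 cell cycle and 34 fatty acid oxidation genes, 0 passed limma at 4 weeks (0 adjusted over the list alone, except 1 cell cycle gene that was lower). At an unadjusted p under 0.05, 7 matrix genes were higher and 7 lower, 0 cell cycle genes higher and 1 lower, and 0 genes of fatty acid oxidation higher and 2 lower. Camera did not pass (adjusted p = 0.91, 0.32 and 0.087 in the same order). The matrix median of 0.02 was -0.18 without heart 4 and 0.18 without heart 8. The cell cycle median of 0.08 was 0.39 without heart 3, where camera passed (adjusted p = 0.0026), and -0.13 without heart 41. Fatty acid oxidation, with a median of -0.11, passed with quantile normalization (-0.18, camera adjusted p = 2.5e-04) and without heart 3 (-0.13, camera adjusted p = 0.013). The count rested on single hearts: it was 0 without heart 8 and 88 without heart 3. It was 21 without each of hearts 4, 7, 13 and 31, 17 without heart 6, 13 without heart 21, 10 without each of hearts 22 and 23, and 8 without each of hearts 1 and 2. It was 11 with no filter on low values and 4 with only the groups compared, and each gene named here lost its call without heart 8 and with only the groups compared (adjusted p up to 0.48). Ankrd1 and Adprhl1 kept theirs in the other fits without 1 heart, while Kcnd2, Xirp2, Hspa1l, Cacng6, Aqp4, Nrap and Cyp1a1 lost theirs in 6 to 16 of 20 such fits and with no filter.

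The responses to TAC in the 2 genotypes shared genes. Of the genes called higher, 403 were called in both genotypes against 81.4 for independent lists, and of those called lower 541 against 99.1; 3 genes were called higher in control and lower in CKO or the reverse. No library was common to both comparisons. Across the 12589 genes, which are not independent replicates, Pearson's r between the responses was 0.60.

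Whether TAC acted differently in CKO hearts was tested as the difference between the 2 responses. By limma's test of the difference, 26 of 46 matrix genes and 3 of 19 foetal genes had a lower response in CKO than in control hearts. Comp (chromosome 8, 70373558 to 70382066), a matrix protein of cartilage and tendon, was 12.0 ± 4.43 FPKM (SD, n = 4) in control TAC hearts and 0.595 ± 0.549 (SD, n = 4) in CKO TAC hearts. In the sham hearts it was 0.985 ± 0.344 and 0.743 ± 0.282. The difference of its responses was -3.29 ± 0.46 (log2, SE, limma adjusted p = 0.0034). Ces1d was 9.18 ± 3.66 FPKM after TAC in control and 41.5 ± 19.1 in CKO hearts, and its responses differed by 2.03 ± 0.28 (limma adjusted p = 0.0034).

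In all, 157 genes passed limma for the difference of responses, 42 higher and 115 lower. Of these, 155 were also called for TAC in control hearts, all with the opposite sign; both tests use the control libraries, so some of that overlap comes with the shared samples. Among the named genes with a smaller rise in CKO hearts were Nppa at -2.91 ± 0.55 (limma adjusted p = 0.020), Sprr1a at -2.53 ± 0.50, Cilp at -2.52 ± 0.39, Fmod at -2.49 ± 0.48 and Angptl7 at -2.47 ± 0.34. Also among them were Ltbp2 at -2.41 ± 0.31 (limma adjusted p = 0.0029), the osteopontin gene Spp1 at -2.36 ± 0.49 and Mfap4 at -2.18 ± 0.32. Higher differences were found for the muscle chloride channel gene Clcn1 at 1.43 ± 0.20, Klhl33 at 1.398, Efemp1 at 1.31 and the muscle sodium channel gene Scn4a at 1.13. Others were Klhl38 at 1.13, Bcl2l11 at 1.12, Plxnb1 at 1.11, Armc2 at 1.01 and Pfkfb1 at 0.98 ± 0.16. Des, which encodes desmin, stood at -0.63 ± 0.08 and Dio2, a thyroid hormone deiodinase gene, at -1.80 ± 0.23.

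Of 46 matrix genes, 26 had a lower response in CKO hearts and 0 a higher one (33 and 0 adjusted over the list alone), with a median of -0.93, Postn at -1.81 ± 0.23, Eln at -1.199 ± 0.13 and Tgfb3 at -1.03 ± 0.12. Camera passed under both correlations (adjusted p = 8.8e-40; adjusted p = 0.034 with an estimated correlation). Of 19 foetal genes, 3 were lower and 0 higher (11 and 0 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 1.7e-10; adjusted p = 0.29 with an estimated correlation). Xirp2 stood at -1.09 ± 0.18 and the ubiquitin hydrolase gene Uchl1 at -1.57 ± 0.31. Fibroblast markers had 4 of 18 lower and 0 higher (5 and 0 adjusted over the list alone), with Serpinf1 at -0.98 and Mmp2 at -0.95 (camera adjusted p = 4.8e-06; adjusted p = 0.30 with an estimated correlation). The fibroblast median was -0.32, with -0.19 without heart 7 and -0.204 without heart 13. In fatty acid oxidation 1 of 34 was higher, Ech1 at 0.63 ± 0.11, and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 1.3e-07; adjusted p = 0.55 with an estimated correlation). For oxidative phosphorylation 0 of 76 passed (0 adjusted over the list alone, and 20 higher at an unadjusted p under 0.05 in limma), with a median of 0.17 (camera adjusted p = 1.2e-08; adjusted p = 0.55 with an estimated correlation). That median was 0.11 without heart 7 or without the hearts with high Myl7, and without the latter the median of fatty acid oxidation was 0.13 against 0.25.

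In all, 20 of 37 lists passed camera for this difference, 1 of them with an estimated correlation. Among them, 0 of 18 genes of the endoplasmic reticulum stress response passed limma (0 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 3.0e-05, and 0.55 with an estimated correlation). At an unadjusted limma p under 0.05, 11 responses were higher. In CKO against control at that p, 13 genes were lower in sham hearts, and 1 higher and 1 lower in TAC hearts. The macrophage list had 0 of 25 past limma (2 lower adjusted over the list alone, and 1 higher and 3 lower at an unadjusted p under 0.05) and a median of -0.27 (camera adjusted p = 0.030; adjusted p = 0.69 with an estimated correlation). Its call ended without heart 2, 3, 4, 13, 14, 16 or 32 and without the hearts with high Myl7 (adjusted p up to 0.99). That median was -0.06, -0.17 and -0.08 without hearts 3, 4 and 16, -0.45 without heart 12 or 41, and -0.01 without the hearts with high Myl7. For the tricarboxylic acid cycle 0 of 19 passed limma (0 adjusted over the list alone, and 0 at an unadjusted p under 0.05), with a median of 0.13 (camera adjusted p = 0.026; adjusted p = 0.67 with an estimated correlation). Its call ended without heart 2, 3, 7, 11, 13, 14 or 16 (adjusted p up to 0.31) and without the hearts with high Myl7 (0.03, adjusted p = 0.99). The median was 0.07 without heart 7 or 13, 0.06 without heart 14, 0.21 without heart 15 and 0.201 without heart 31.

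**Figure D3:**
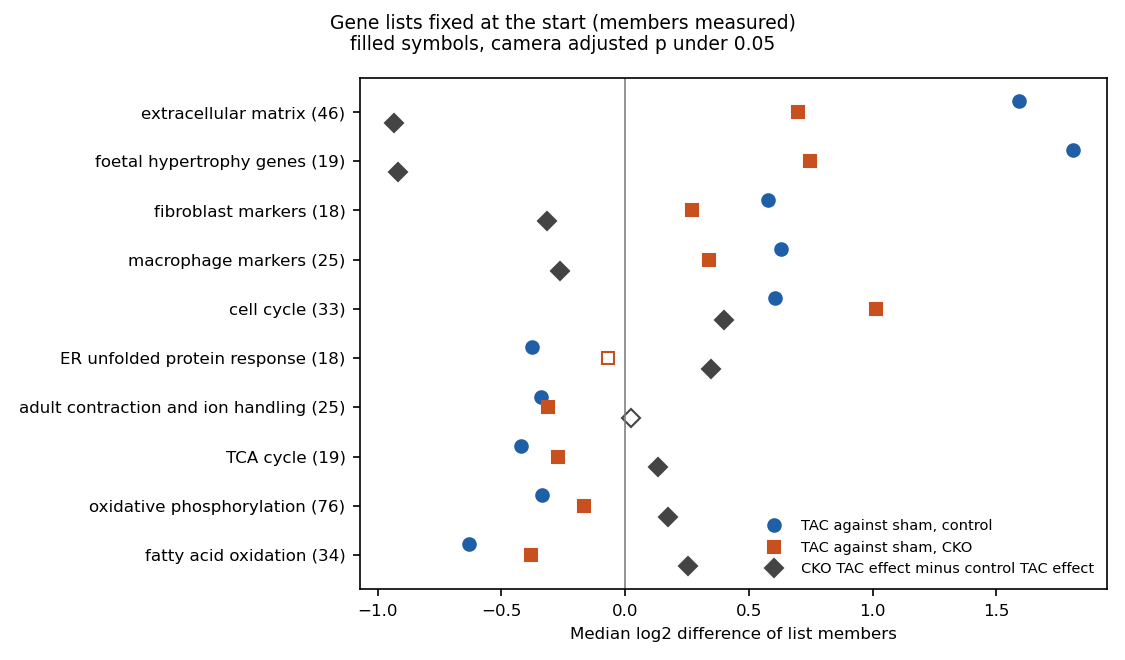
Median log2 difference of the members of 10 gene lists for TAC against sham in control hearts, in CKO hearts, and for the difference between them, each as a mean of 2 and 4 weeks; filled points passed camera at an adjusted p under 0.05. The matrix list stood at 1.59, 0.70 and -0.93, and the cell cycle list at 0.61, 1.01 and 0.40.

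As a mean of both times, the cell cycle list had a median difference of responses of 0.40. Of 33 members 0 passed (1 higher adjusted over the list alone, and 4 higher at an unadjusted p under 0.05 in limma; camera adjusted p = 2.3e-04; adjusted p = 0.60 with an estimated correlation). Without heart 31 this list did not pass (median 0.15, adjusted p = 0.10). Its median was 0.64, 0.23 and 0.24 without hearts 13, 32 and 41, and 0.62 without the hearts with high Myl7. The cell cycle list did not pass with a filter of 3 FPKM (median 0.30, adjusted p = 0.24).

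By time, the median response of the cell cycle list was 0.82 in control and 1.97 in CKO hearts at 2 weeks, and 0.37 in control and 0.08 in CKO hearts at 4 weeks. In control hearts the list passed camera at 2 weeks (adjusted p = 2.0e-05; adjusted p = 0.55 with an estimated correlation) and at 4 weeks (adjusted p = 0.015; adjusted p = 0.75 with an estimated correlation). The 2-week call ended with a filter of 3 FPKM (0.25, adjusted p = 0.11) and without the hearts with high Myl7 (0.49, adjusted p = 0.12), and the median was 0.54 without heart 11. The 4-week call ended with that filter (0.19, adjusted p = 0.15), without heart 2 (0.31, adjusted p = 0.051) and without heart 7 (0.21, adjusted p = 0.21). That median was 0.66 without heart 6 and 0.65 with a pseudocount of 0.1. The difference between genotypes in the change with time, a comparison added after the data were seen, had a median of -1.24 for the cell cycle (camera adjusted p = 3.5e-13; adjusted p = 0.54 with an estimated correlation). In limma 0 of 33 passed (5 lower adjusted over the list alone, and 13 lower at an unadjusted p under 0.05). For the matrix the median was -0.43 (camera adjusted p = 2.5e-07; adjusted p = 0.54 with an estimated correlation), and 0 of 46 passed limma (0 adjusted over the list alone, and 11 lower at an unadjusted p under 0.05). Without heart 13 these medians were -1.89 and -0.66, and that of the cell cycle was -0.72 without heart 31 and -0.51 with a filter of 3 FPKM.

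Among 21 Wnt ligands, receptors and antagonists, 2 were lower and 0 higher (4 and 0 adjusted over the list alone; median -0.09, camera adjusted p = 0.028; adjusted p = 0.55 with an estimated correlation). Both, Frzb at -1.25 ± 0.23 and Sfrp1 at -1.02 ± 0.21, encode secreted Wnt antagonists. The Wnt list did not pass camera without heart 1, 8, 12, 31, 32 or 41 (adjusted p up to 0.19), or with no filter (adjusted p = 0.067), and its median lay between -0.18 and -0.01 over the settings. Of 22 YAP and TEAD targets, 1 was lower, Ccdc80 at -0.52 ± 0.11, and 0 higher (4 and 1 adjusted over the list alone), and camera did not pass (adjusted p = 0.33).

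The count of 157 was 75, 76, 77, 79, 80, 81, 89 and 102 without hearts 14, 16, 7, 1, 32, 8, 13 and 41, and 97 with only the groups compared. Without the hearts with high Myl7 it was 18, and the genes named for this comparison then missed the threshold, Comp with -3.09 (limma adjusted p = 0.058) and Ces1d with 2.01 (limma adjusted p = 0.070) among them, except Angptl7, Clcn1, Eln, Tgfb3, Des and Dio2. Comp, Cilp, Angptl7, Ltbp2, Mfap4, Ces1d, Postn and Eln passed in each fit without 1 heart. The call of Nppa ended without heart 1, 7, 8, 32 or 41 (adjusted p up to 0.061), that of Fmod without 2, 7, 8, 14, 31 or 41, that of Frzb without 8, 14 or 32 and that of Bcl2l11 without 1, 7, 8, 13 or 16. Sprr1a, Spp1, Klhl33, Armc2, Uchl1, Sfrp1 and Ccdc80 each lost theirs in 9 to 17 of 20 such fits (adjusted p up to 0.11). These 7 genes, and Fmod with a pseudocount of 0.1, also missed the threshold under at least 1 of the settings for the filter, the pseudocount, the trend, the scaling or the groups fitted (adjusted p up to 0.17).

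**Figure D4:**
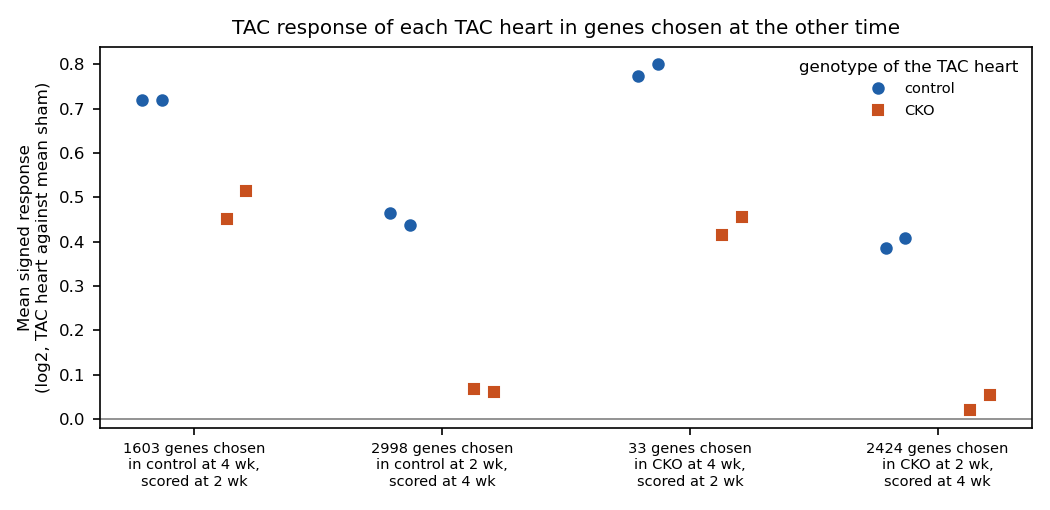
Mean TAC response (log2) of each TAC heart against the sham mean of its own genotype and time. Each gene was signed by the direction of its change. The genes were chosen at the other time point in control or in CKO hearts, and each point is a heart. For genes chosen in control hearts the means were 0.72 in control and 0.48 in CKO hearts at 2 weeks, and 0.45 and 0.06 at 4 weeks.

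CKO and control hearts were also compared directly after TAC. Limma called 434 genes, 150 higher and 284 lower in CKO hearts. Lower were Comp at -3.54 ± 0.32 (log2, SE, limma adjusted p = 1.0e-04), Fmod at -2.67 ± 0.34, Sprr1a at -2.59, Thbs4 at -2.51 and Nppa at -2.49 ± 0.39 (limma adjusted p = 0.0033). So were Spp1 at -2.49, Ltbp2 at -2.28, Cilp at -2.15 and Angptl7 at -2.05. Higher, beside Esr1, were Ces1d at 2.07 ± 0.20 (limma adjusted p = 1.1e-04), Retnla at 1.81 ± 0.34, Klhl33 at 1.38, Acot1 at 1.201, Efemp1 at 1.17, Dbh, the enzyme that makes noradrenaline, at 1.17, Map2k6 at 1.00 and Plxnb1 at 0.97. The acute-phase gene Serpina3n was lower too, at -1.79.

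Of 46 matrix genes, 28 were lower and 0 higher in CKO TAC hearts (34 and 0 adjusted over the list alone), with a median of -0.65 and Eln at -0.96 ± 0.09. Camera passed under both correlations (adjusted p = 6.6e-36; adjusted p = 0.048 with an estimated correlation). Of 19 foetal genes, 9 were lower and 0 higher (14 and 0 adjusted over the list alone), with a median of -1.02 and Xirp2 at -1.13 ± 0.12 (camera adjusted p = 5.9e-12; adjusted p = 0.21 with an estimated correlation). Among 34 genes of fatty acid oxidation 4 were higher and 0 lower (11 and 0 adjusted over the list alone), with Ech1 at 0.46 ± 0.08 (camera adjusted p = 7.8e-07; adjusted p = 0.55 with an estimated correlation). The median of that list was 0.19, and 0.13 without heart 13. Among 21 Wnt genes 4 were lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.0012; adjusted p = 0.36 with an estimated correlation). They were Frzb at -1.06 ± 0.16, Sfrp2 at -1.41 ± 0.25 and Sfrp1 at -0.78 ± 0.15, which encode secreted Wnt antagonists, and Dkk3 at -1.77 ± 0.40. The median of the Wnt list was -0.13, with -0.22 without heart 2 and -0.09 without heart 41. Dkk3 is also on the atrial list. Of 22 YAP and TEAD targets, 4 were lower and 1 higher (6 and 3 adjusted over the list alone), and camera did not pass (adjusted p = 0.22). Of 35 interferon genes, 0 passed (0 adjusted over the list alone, and 1 higher at an unadjusted p under 0.05 in limma), with a median of 0.45 (camera adjusted p = 4.6e-04; adjusted p = 0.71 with an estimated correlation). Without heart 41 that median was -0.0495 (camera adjusted p = 0.66), and without heart 3 it was 0.90. The count of 434 was 202, 210, 225 and 272 without hearts 1, 32, 41 and 13, and 124 with only the groups compared. Acot1 lost its call without heart 1, 3, 11, 13 or 41, Map2k6 without 1, 13 or 32, Retnla without 32 or 41, Sfrp1 without 1, and Dkk3 in 8 of 20 such fits (adjusted p up to 0.14). Acot1, Dbh, Map2k6, Retnla and Serpina3n did not pass with only the groups compared (adjusted p up to 0.18), nor Acot1 and Dkk3 with no filter, nor Acot1 without the hearts with high Myl7.

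Split by time, a comparison added after the data were seen, 52 genes differed between CKO and control TAC hearts at 2 weeks in limma, 12 higher and 40 lower. Sprr1a at -3.10 ± 0.50, Comp at -2.86 ± 0.46 and the clusterin gene Clu at -1.72 ± 0.12 (limma adjusted p = 7.1e-06) were lower, and the mitotic genes Cep55 at 1.59 ± 0.25 and Kif20a at 1.55 ± 0.28 higher. Of 33 cell cycle genes, 1 was higher and 0 lower (27 and 0 adjusted over the list alone). Their median was 1.32 (0.602 with a filter of 3 FPKM, 0.88 without heart 31). Camera gave adjusted p = 1.2e-22 (0.22 with an estimated correlation). Endothelial markers had 9 of 23 higher and 0 lower at unadjusted limma p under 0.05. At 4 weeks 105 genes differed, 29 higher and 76 lower. Comp stood at -4.23 ± 0.46, Fmod at -3.61 ± 0.48, Spp1 at -3.10 ± 0.49, the serum amyloid gene Saa3 at -2.71 ± 0.43, Retnla at 2.68 ± 0.48 and Ces1d at 2.40 ± 0.28. Of 46 matrix genes, 19 were lower and 0 higher at 4 weeks (32 and 0 adjusted over the list alone; camera adjusted p = 1.5e-36; adjusted p = 0.045 with an estimated correlation). The 2-week count was 5 without heart 32, 7 without heart 31 and 119 without heart 11. It was 110 with quantile normalization, 43 higher and 67 lower, 98 with no filter, 96 with a pseudocount of 1, 33 without the hearts with high Myl7 and 9 with only the groups compared. Comp did not pass at 2 weeks without heart 11 or 31, nor Sprr1a, Cep55 and Kif20a without heart 31 or 32 (adjusted p up to 0.28). Comp, Sprr1a and Cep55 missed the threshold at 2 weeks without the hearts with high Myl7, Cep55 and Kif20a with a pseudocount of 0.1, and these genes and Clu with only the groups compared (adjusted p up to 0.44). The 4-week count was 19, 33, 46 and 176 without hearts 1, 41, 2 and 3, 63 without the hearts with high Myl7 and 2 with only the groups compared. Spp1, Saa3 and Retnla did not pass without heart 1, 2 or 41 (adjusted p up to 0.21). With only the groups compared, the 6 genes named at 4 weeks missed it (adjusted p up to 0.27), as did Spp1 with a pseudocount of 0.1, where Saa3 was -4.84.

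CKO and control hearts without overload, before any operation and after sham, differed in few genes. At the end of tamoxifen 2 genes passed limma, Esr1 at 9.73 ± 0.29 and the small nucleolar RNA Snora3 (chromosome 7, 109520120 to 109520251), which was listed at 0 FPKM in both CKO hearts, and 431 genes had an unadjusted p under 0.05. A gene listed at 0 is not shown to be silent in these files, since the housekeeping genes Gapdh and Ppia are also listed near 0. In sham hearts Esr1 alone passed limma, at 10.09 ± 0.21, and 518 genes had an unadjusted p under 0.05. The test of a change between these stages called 1 gene, Snora3, again chosen after its values were seen, with 341 at an unadjusted p under 0.05.

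Of 18 genes of the endoplasmic reticulum stress response, 0 passed in sham hearts over all genes in limma, 13 were lower in CKO hearts adjusted over the list alone, and 13 were lower at an unadjusted p under 0.05. The median was -0.28 (camera adjusted p = 5.6e-15; adjusted p = 0.61 with an estimated correlation). Of 46 matrix genes, 0 passed in sham hearts in limma (0 adjusted over the list alone, and 7 higher at an unadjusted p under 0.05), with a median of 0.20 (camera adjusted p = 1.1e-08; adjusted p = 0.67 with an estimated correlation). Without heart 7 these medians were -0.16 for the stress response and 0.13 for the matrix, and without heart 8 that of the matrix was 0.12. At the end of tamoxifen 0 of 13 atrial markers passed over all genes in limma (1 adjusted over the list alone, and 4 higher at an unadjusted p under 0.05). Their median was 0.28 and their mean 1.79 (camera adjusted p = 5.6e-06; adjusted p = 0.53 with an estimated correlation). Both CKO hearts of that stage had high atrial transcripts, with the atrial myosin light chain gene Myl7 at 323 FPKM in heart 21 and 50.6 FPKM in heart 24. The count in sham hearts was 8 without heart 6, 4 without heart 14 and 2 without each of hearts 7, 15, 22 and 23. It was 5 without the hearts with high Myl7, 3 with no filter and 2 with only the groups compared. The count at the end of tamoxifen was 7 without heart 23 and 4 without heart 21, 5 with no filter and 4 with only the groups compared. That of the change between stages was 7, 5, 3 and 3 without hearts 23, 14, 6 and 21, and 2 without each of hearts 7, 15, 22 and 24, with 4 and 2 under the same 2 settings.

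**Figure D5:**
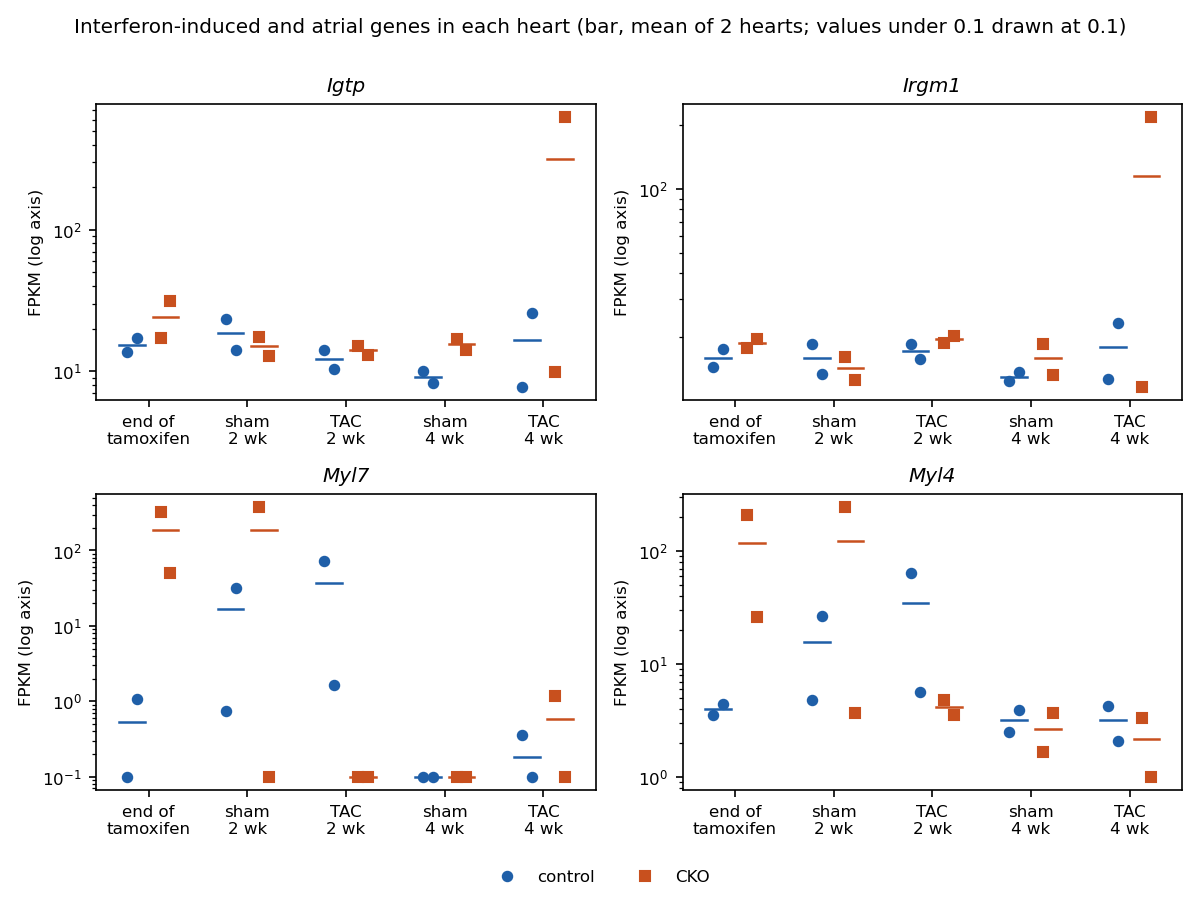
FPKM (log axis, values under 0.1 drawn at 0.1) of Igtp and Irgm1, interferon-gamma genes, and of Myl7 and Myl4, atrial light chain genes, in each of the 20 hearts, with a bar at the mean of the 2 hearts of a group. Heart 41 stood apart with Igtp at 623 FPKM, and 5 hearts had Myl7 of 32.2 to 372 FPKM against at most 1.66 FPKM in the other 15.

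Averaged over all 5 stages, 19 genes differed between genotypes in limma, 3 higher and 16 lower in CKO hearts, and 1082 had an unadjusted p under 0.05. Esr1 and Prkg1, a cyclic GMP-dependent kinase gene, at 0.51 ± 0.09 (limma adjusted p = 0.044), were separated between the genotypes at every stage. Ces1d was higher, at 0.83 ± 0.13. Comp at -1.41 ± 0.20 (limma adjusted p = 0.017), Thbs4 at -1.06 ± 0.17, Ltbp2 at -0.77 ± 0.14, Xirp2 at -0.50 ± 0.08, Clu at -0.48 ± 0.05 and Des at -0.28 ± 0.04 were lower. Ces1d, Clu and Des were chosen after their values were seen. The count was 6 without heart 8, 7 without each of hearts 7, 15 and 32, 8 without heart 31, 10 without heart 13, 12 without each of hearts 4 and 16, 34 without heart 11 and 53 without heart 3. It was 8 with a pseudocount of 0.1 or a filter of 3 FPKM, 11 without a trend and 12 with quantile normalization. Prkg1, Ltbp2, Thbs4 and Xirp2 lost their calls in 10 to 17 of 20 fits without 1 heart, Comp without heart 7, 8 or 15 and Ces1d without heart 8, 13, 15, 31 or 32 (adjusted p up to 0.13). Prkg1, Ltbp2, Thbs4 and Xirp2 also missed the threshold with no filter, and Des with quantile normalization (-0.21, adjusted p = 0.055).

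The last comparison asked whether the response to TAC differed between 4 and 2 weeks, as a mean of both genotypes. In that mean, the response of matrix, fibroblast and cell cycle genes was lower at 4 weeks, and that of oxidative phosphorylation and fatty acid oxidation higher. Ucp3, a mitochondrial uncoupling protein of muscle, was 4.14 ± 0.238 FPKM (SD, n = 2) in control TAC hearts at 2 weeks and 14.5 ± 2.38 (SD, n = 2) at 4 weeks. In the matched sham hearts it was 24.0 ± 3.79 and 19.8 ± 4.93. Limma called 1675 genes, with 853 responses higher and 822 lower at 4 weeks. Higher were Lgals6 at 3.76 ± 1.01, Lypd2 at 2.74 ± 0.66, Ucp3 at 1.74 ± 0.30 (limma adjusted p = 0.0059) and Pdk4, the kinase that turns off pyruvate dehydrogenase, at 1.45 ± 0.33. Lower were the mitotic genes Ccnb2 at -2.23 ± 0.46 and Fam64a at -2.00 ± 0.46, and Postn at -1.91 ± 0.23. So were the mast cell protease genes Tpsb2 at -1.87 ± 0.26 and Cma1 at -1.82 ± 0.38, Eln at -1.83 ± 0.13 (limma adjusted p = 1.5e-05), Top2a at -1.77 ± 0.47 and the fibronectin gene Fn1 at -1.76 ± 0.18.

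Of 46 matrix genes, 33 had a lower and 1 a higher response at 4 weeks (37 and 1 adjusted over the list alone), with a median of -1.01 (camera adjusted p = 9.9e-21; adjusted p = 0.14 with an estimated correlation). Fibroblast markers had 15 of 18 lower and 0 higher (15 and 0 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 7.6e-11; adjusted p = 0.14 with an estimated correlation). Of 33 cell cycle genes, 16 were lower and 0 higher (20 and 0 adjusted over the list alone), with a median of -1.03 and Kif23 at -1.72 (camera adjusted p = 2.3e-11; adjusted p = 0.38 with an estimated correlation). Of 76 oxidative phosphorylation genes, 52 were higher and 0 lower (70 and 0 adjusted over the list alone), with a median of 0.40 and Cox6a2 at 0.71 ± 0.10 (camera adjusted p = 1.3e-23; adjusted p = 0.31 with an estimated correlation). Of 34 genes of fatty acid oxidation, 21 were higher and 0 lower (31 and 0 adjusted over the list alone), with a median of 0.53 and Ech1 at 0.86 ± 0.11 (camera adjusted p = 4.1e-16; adjusted p = 0.28 with an estimated correlation). Hippo pathway components had 7 of 26 lower and 0 higher (10 and 0 adjusted over the list alone; median -0.27, camera adjusted p = 2.8e-04; adjusted p = 0.38 with an estimated correlation). With quantile normalization the medians were 0.09 for oxidative phosphorylation and 0.34 for fatty acid oxidation, and Ech1 stood at 0.46 and Cox6a2 at 0.39. With a filter of 3 FPKM the cell cycle median was -0.29 (camera adjusted p = 0.044). At 4 weeks alone and an unadjusted p under 0.05, in control hearts 39 matrix, 6 fibroblast and 8 cell cycle genes were higher and 2, 2 and 1 lower, with 18 genes of oxidative phosphorylation and 22 of fatty acid oxidation lower and 2 and 1 higher. In CKO hearts, where 0 genes of these lists passed limma, the counts were 7, 0 and 0 higher and 7, 4 and 1 lower, with 1 and 2 lower and 5 and 0 higher. Counts of separate tests do not test a difference between genotypes; CKO against control TAC hearts at 4 weeks had 0 cell cycle genes higher or lower at that p. On the Hippo list, Vgll3 stood at -1.11 and Wwtr1, which encodes the YAP paralogue TAZ, at -0.50.

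The count of 1675 was 762, 778, 781, 919, 967, 1001 and 1022 without hearts 6, 15, 31, 16, 8, 32 and 2, and 676 without the hearts with high Myl7. Lypd2 was 4.403 with a pseudocount of 0.1 and lost its call without heart 6 or 15, and Lgals6 and Top2a in 9 of 20 such fits (adjusted p up to 0.075). Without the hearts with high Myl7, Ccnb2, Fam64a, Cma1, Pdk4, Lypd2, Lgals6 and Top2a did not pass (adjusted p up to 0.16), nor did Lgals6 with no filter or Top2a with only the groups compared. Whether the genotypes differed in this change with time, a comparison added after the data were seen, gave 0 genes in limma and 818 at an unadjusted p under 0.05. The smallest p values, none passing, were those of Saa3 at -5.87, Clu at 1.35, Tmem29 at 1.497, Cep55 at -2.50 and H1f0 at -0.96. That count was 4 without heart 3 or 41, 3 without heart 14, 2 without each of hearts 1, 6 and 15, and 1 without each of hearts 2, 7, 11, 21, 22, 23, 24 and 31. It was 7 without the hearts with high Myl7, 3 with no filter and 2 with only the groups compared.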

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

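In this part, the counts over other splits of the hearts, the fits without the hearts with high Myl7 and the tests on heart 41 and on the source of atrial transcripts were chosen only after the result was seen, as were those of the lowest count without 1 heart, of quantile normalization and of a single factor.

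The response to TAC differed between genotypes in 157 genes by limma's test of the difference itself, and so did 20 of 37 lists by camera, 10 of which the report describes. Their median log2 differences of responses were -0.93 for the matrix, -0.92 for foetal and overload genes, 0.25 for fatty acid oxidation, 0.17 for oxidative phosphorylation, 0.40 for the cell cycle (0.15 without heart 31, where it did not pass), -0.32 for fibroblast markers, 0.35 for the endoplasmic reticulum stress response, -0.27 for macrophage markers, 0.13 for the tricarboxylic acid cycle and -0.0918 for Wnt ligands and receptors; with an estimated correlation only the matrix list passed (camera adjusted p = 0.034). In a fit of the 16 operated hearts the real grouping called 97 genes, and of 100 splits drawn, the real one included, 1 gave as many, the highest other giving 55, so chance can be excluded at that level. In the TAC hearts alone, CKO against control called 152 genes with time in the fit, 1 of 34 splits gave as many and the highest other gave 1. Without time in the fit it called 6, and 2 of 35 splits gave as many, so chance cannot be excluded in that fit. The split with 1669 genes is that of 2-week against 4-week hearts, which points to time as a structure of the samples.

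The weaker response in CKO hearts was not a matter of 1 heart, since the lowest count without 1 heart was 75 genes, without heart 14, nor of library scaling, since quantile normalization gave 172. It held in genes called at the other time: in 4 of 4 sets, from control or CKO hearts, the mean response was smaller in CKO hearts, a test written beforehand. They were called in a fit with the hearts compared, and the 2 sets of a time share hearts. The 33 genes of CKO hearts at 4 weeks, against 1603 to 2998 in the others, rested on single hearts. Whether the responses differ by 1 common factor cannot be told apart: with the factor of the matrix list, 0.384, the cell cycle list stood 0.72 ± 0.22 (log2, SE) above its expected value in CKO hearts, but it was picked out of 36 lists for going the other way. The excess was that of 2 weeks, 1.33 ± 0.33 (0.93 ± 0.30 without heart 31), and at 4 weeks it was 0.06 ± 0.28. A smaller pressure load in CKO mice stays open, since gradients are not given here, as does an effect of the Cre transgene, which controls lack. An effect of Wnt5a remains a hypothesis.

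Interferon-gamma genes were far higher in heart 41 than in the other 19 hearts: Igtp at 623 FPKM (others at most 31.2), Irgm1 at 218 (23.1), Gbp2 at 86.9 (20.2) and Cd274 at 43.5 (8.62). A wrong genotype label is argued against by Esr1 at 752 FPKM, and a wrong operation label by Ankrd1 at 2228 FPKM, above the 1253 FPKM of the highest heart without TAC. More macrophages stay open: the marker mean lay -0.36 (log2) from the highest heart, of another stage, but was 3.86 against 3.05 in heart 3. More T and NK cells cannot be told apart from an interferon response of the heart's own cells, since their marker mean was 0.28 above the highest other heart but its members lay near the floor, with Nkg7 at 2.47 against at most 2.32 FPKM. Other biological causes, such as an infection of this mouse, were not tested, since the design names none.

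Atrial transcripts were high in 5 hearts, with Myl7 at 372 FPKM in heart 14, 323 in heart 21, 72.6 in heart 11, 50.6 in heart 24 and 32.2 in heart 16, and at most 1.66 in the other 15. Of 12 other atrial markers, 3 (Myl4, Sln and Mybphl) had the same 5 highest hearts, in line with atrial tissue in those samples, and genotype as the cause is argued against by 2 control hearts among the 5. Leaving out the 3 operated ones was set against 7 other removals from the same groups, a test written beforehand. Hearts 21 and 24 were left out in each. For the difference of responses 2 left as few genes, both without heart 14, so it decides nothing. Without the hearts with high Myl7 all 157 genes kept their sign and a median of 0.971 of their log2 difference (lowest 0.739). The SE grew 1.18 times, and without heart 14 alone the median was 0.982. That argues against atrial tissue as the cause. For some lists it stays open, since without those hearts the median difference of responses was -0.01 for macrophage markers, 0.03 for the tricarboxylic acid cycle and 0.13 for fatty acid oxidation.

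The response to TAC differed between 4 and 2 weeks in 1675 genes in limma. In list medians it was -1.01 for the matrix, 0.40 for oxidative phosphorylation, 0.53 for fatty acid oxidation, -1.03 for the cell cycle, -0.76 for fibroblast markers and -0.27 for Hippo components, and 0 of 37 lists passed camera with an estimated correlation (adjusted p = 0.14 to 0.38 for these). Quantile normalization gave 0.09 for oxidative phosphorylation and a filter of 3 FPKM -0.29 for the cell cycle. Between genotypes this change with time differed by -0.43 for the matrix and -1.24 for the cell cycle, in a comparison added after the data were seen, with 0 genes in limma and 818 at an unadjusted p under 0.05. Neither list passed camera with an estimated correlation (adjusted p = 0.54 for both), and the cell cycle value was -0.51 with a filter of 3 FPKM and -0.72 without heart 31. In a fit of the operated hearts the real grouping called 1191 genes, and 2 of 100 splits gave as many, the real included. The other (1812) kept TAC hearts split by time and mixed sham hearts, so the count decides nothing. The change of the genotype difference between the end of tamoxifen and sham held for 1 gene, Snora3, by the same kind of test.

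Fits of the compared hearts alone gave these counts within groups. TAC against sham in control hearts called 2332 genes without time in the fit and 2949 with it; 1 of 35 and 1 of 34 splits gave as many and the highest other gave 2 in each, so chance can be excluded. In CKO hearts the same fits, which hold 1 TAC effect for both times, called 0 genes in limma, with 1650 and 1999 at an unadjusted p under 0.05. With 0 in the real grouping, all 35 of 35 and 34 of 34 splits give as many by construction (1 and 4 in the highest other), so these counts decide nothing. In the model of the 20 hearts 1147 genes passed, of which 403 higher and 541 lower were shared with control hearts. CKO against control in sham hearts called 1 gene, with 7 of 35 and 5 of 34 splits giving as many and 3 in the highest other. A count of 1 decides nothing on a single gene such as Esr1, which in the model of the 20 hearts stood at 10.09 (limma adjusted p = 1.0e-12), with no overlap between the genotypes. Over all stages 19 genes were called, with 5 of 100 splits giving as many and 52 in the highest other, so chance cannot be excluded for that count, Esr1 apart.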

How the results depend on the processing

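In this part, the fits without the hearts with high Myl7 (10 FPKM or more) and the 3 added comparisons were chosen only after the results were seen; the other settings were chosen before. Of the named gene results, the direction was kept under each setting run, and the side of the threshold changed for 14 results with a pseudocount of 0.1 (194 did not), 1 with 1 FPKM (207 did not), 21 with no filter (187), 1 with a filter of 3 FPKM (154), 1 with median-ratio scaling (207), 6 with quantile normalization (202), 7 without a trend (201), 49 with only the groups compared (149) and 48 without the hearts with high Myl7 (148). Over the fits without 1 heart 3824 gene results were unchanged in call, 334 lost it and 2 gained it. Of 63 list results, 52 lost their call with an estimated correlation, only matrix results kept theirs, and the rest had none. Values near the floor are limited by depth, which differed by a ratio of 1.37 between libraries. No fit with sex was run. Fits of only the groups compared for the mean of all 5 stages, and fits without the hearts with high Myl7 for that mean, for the end of tamoxifen and for the change between stages, could not differ or could not be run and gave no value.

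Counts of called genes moved by more than 1.5 times as follows. With a pseudocount of 0.1, CKO against control over all stages gave 8; with 1, CKO against control in 2-week TAC hearts gave 96. With no filter, TAC in CKO hearts at 4 weeks gave 11, CKO against control 5 at the end of tamoxifen, 3 in sham and 98 in 2-week TAC hearts, the change between stages 4 and the difference between genotypes in the change with time 3. With a filter of 3 FPKM, CKO against control over all stages gave 8, without a trend 11 and with quantile normalization 12, and quantile normalization gave 110 in 2-week TAC hearts. The cause was not tested. With only the groups compared, which leaves fewer hearts to estimate the spread, TAC in CKO hearts gave 313 over both times, 15 at 2 and 4 at 4 weeks; TAC in control hearts 1158 at 2 and 355 at 4 weeks; CKO against control 4 at the end of tamoxifen, 2 in sham and 124 in TAC hearts, 9 at 2 and 2 at 4 weeks; the difference of responses between genotypes 97; the change between stages 2; and the difference between genotypes in the change with time 2. Without the hearts with high Myl7, TAC in control hearts gave 2383 over both times and 1119 at 2 weeks, TAC in CKO hearts 728, CKO against control 5 in sham and 33 and 63 in TAC hearts at 2 and 4 weeks, the difference of responses between genotypes 18, between times 676, and between both 7.

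Without 1 heart, the counts ran from 351 to 1215 for TAC in CKO hearts, 465 to 2453 at 2 weeks and 0 to 88 at 4 weeks; from 1618 to 3014 for TAC in control hearts at 2 weeks and 660 to 1632 at 4 weeks; for CKO against control from 6 to 53 over all stages, 2 to 7 at the end of tamoxifen, 1 to 8 in sham hearts, 202 to 484 in TAC hearts, 5 to 119 at 2 weeks and 19 to 176 at 4 weeks; from 75 to 182 for the difference of responses between genotypes, 762 to 2045 between times and 0 to 4 between both; and from 1 to 7 for the change between stages. Fewer hearts were fitted in each. In 7 cases camera's direction for a list turned, and in 4 of them the list's median changed sign. Without heart 41 the interferon median for TAC in CKO hearts at 4 weeks was -0.23 (range without 1 heart -0.23 to 1.60), and for CKO against control in TAC hearts -0.0495 (range -0.0495 to 0.90). The cause is that heart's own interferon values. For TAC in CKO hearts at 4 weeks, where neither list passed, the cell cycle turned without heart 41 (-0.13, range -0.13 to 0.39), and the matrix without heart 4 (-0.18, range -0.18 to 0.18). With a filter of 3 FPKM or without heart 3 only camera's direction turned for the matrix, at medians of 0.0235 and 0.0175 against 0.0180, as it did for the tricarboxylic acid cycle in the difference of responses between genotypes without the hearts with high Myl7 (median 0.0310 against 0.13). The cause was not tested.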

Other observations

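The genes in this part were chosen only after their values were seen. Haemoglobin and haem synthesis transcripts were low in heart 41. Hba-a1, the alpha-globin gene of red cells, was 90.6 FPKM there and at least 588 FPKM in each other heart, and Alas2, the erythroid enzyme of haem synthesis, was 1.46 against at least 11.5 FPKM. Antigen presentation genes were high in the same heart: Cd74 was 541 FPKM against at most 185 FPKM in the others, B2m 3234 against at most 981, and Ciita, the activator of class II genes, 2.48 against at most 0.823.

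The gene of the YAP protein itself differed little after TAC: Yap1 had a log2 difference of -0.03 ± 0.07 (SE) in control hearts and -0.21 ± 0.07 in CKO hearts. These are transcript values and say nothing of the protein's amount or place in the cell. At 2 weeks 696 genes were called higher and 863 lower after TAC in both genotypes (139 and 148 for independent lists, which these are not). At 4 weeks 16 and 10 were (1.21 and 0.892).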
